A study of Mus musculus with 8 samples.

How the data were processed

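Liver RNA from 4 control and 4 VEGF-D knockout mice was measured by sequencing of poly(A)-selected RNA. Per the labels' protocols, the RNA was fragmented by base hydrolysis, tailed, reverse transcribed, circularized and amplified before sequencing. The submitters' processing notes name the mouse genome build mm9, TopHat and HOMER, without versions or roles.

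The authors deposited a table of RPKM, with a column per sample per the file headers, 1 RefSeq transcript for each of 22802 distinct gene symbols, and mm9 coordinates. The same table holds the authors' log2 fold change and the authors' FDR, an adjusted p-value, per the file headers; the tool behind them is not given in the sources used here. The header of the fold change puts control first, but the values are knockout over control. Over 7236 genes with a mean above 5 RPKM, the authors' deposited log2 fold change differed from the log2 ratio of mean RPKM by a median of -0.0517 and by at most 0.0828 around that median.

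Depth was recovered from the RPKM themselves. A gene's RPKM moves in steps of 1 read, whose size depends on transcript length and depth. Transcript lengths of a later annotation (GENCODE M21) were matched by RefSeq identifier for 97.4% of genes, and no coordinates of that annotation were used. Depth came to 3525000, 3774000, 3803000 and 4179000 reads assigned to genes in controls 1 to 4, and to 5605000, 4390000, 4308000 and 3407000 in knockout samples 1 to 4. Of values worth up to 20 reads, 65.0% to 66.9% lay within 0.1 of a whole read, against 20.0% by chance, so read numbers are estimates. Intervals from reads cover counting error only.

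Groups were taken from the labels. The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend and robust moderation, on log2(RPKM + 0.5) without further scaling, for 12865 genes with a mean of at least 0.5 RPKM over all 8 samples. It was two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes. Figf was compared with an exact permutation test over 70 arrangements. The p-values measure the spread between the samples, which the labels call biological replicates.

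Before the data were examined, 39 gene lists, the design, the alternatives and the rule for named genes were fixed. The rule named Figf, 15 genes of remnant handling, the 10 largest rises and 10 largest falls past the threshold with complete separation of the groups, up to 4 members of each list, and passing neighbours of Figf; symbols of unnamed transcripts and small RNAs were left out. Members named outside this rule, where a list had 5 or fewer calls, are said to be named after their values were seen. The 36 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry; 7 of 968 list members were not in the table. List scores were the mean of log2 values centred per gene.

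The test was tested on simulated data with the measured means and spreads of 12865 genes, with 50 genes changed at each of 4 fold sizes. It called 34% of genes simulated at a log2 fold change of 0.5, 84% at 1, 98% at 2 and 88% at -1, with 6 false calls among 158. For the list test, a shift of -0.4 in the fatty acid oxidation list gave an adjusted p of 5.94e-40, and 1 of 35 other lists was called; genes were simulated as independent.

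The alternatives were pseudocounts of 0.1 and 1, no filter, a mean of at least 1 RPKM, median-ratio scaling, quantile normalization, a total without the 50 highest genes, limma without trend and robust moderation, array weights, the replicate number as a block, every row of the table, a threshold of 0.1 and leaving out each sample. Chosen after seeing the data were limma voom on recovered reads, removal of trends in length, GC content and level, and thinning to the shallowest library, for the 98.0% of tested genes with a length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for depth, tables and plots.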

Results

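Liver RNA was compared between mice lacking vascular endothelial growth factor D (VEGF-D) and control mice, with 4 samples in each group. VEGF-D, encoded by Figf, is a secreted growth factor that acts on lymphatic and blood vessel endothelium. All animals lacked the LDL receptor and made apolipoprotein B only as its full-length form, a background prone to atherosclerosis, and all had eaten a high-fat diet for 12 weeks. The title of the series concerns blood lipids and the clearance of chylomicron remnants, the particles left after intestinal fat has been partly digested in the circulation. Each sample is described as a biological replicate. Expression was given as RPKM for 22802 genes, and the depth recovered from the steps of low values was 3407000 to 5605000 reads assigned to genes per sample. At that depth, 1 read of a 2-kb transcript was worth 0.0892 to 0.147 RPKM, so genes under about 1 RPKM rest on few reads.

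The targeted gene was low in every sample. Figf (NM_010216, mm9 chromosome X, 160811480 to 160840579, plus strand) stood at 0.605, 0.565, 0.701 and 0.255 RPKM in the 4 controls and at 0.285, 0.243, 0.124 and 0.157 RPKM in the 4 knockout samples. The means were 0.53 ± 0.193 RPKM (SD, n = 4) and 0.20 ± 0.0746 RPKM (SD, n = 4). The difference on the log2(RPKM + 0.5) scale was -0.54, with an exact two-sided permutation p of 0.0571, where the smallest p that 4 against 4 allows is 0.0286. The recovered reads numbered 15 over the controls and 7 over the knockout samples, a depth-adjusted ratio of 0.403 with a 95% exact binomial interval of 0.139 to 1.05 that covers counting error only. Without control 4, the only control within the range of the knockout samples, the difference was -0.68 and the exact permutation p was 0.0286. Across all samples left out in turn, the exact permutation p reached 0.0857. Reads remained in all 4 knockout samples, and the part of the gene that was deleted is not given in the sources used here, so this measurement checks the labels only weakly. In the authors' deposited table the log2 fold change of Figf was -1.30 with an FDR of 0.395.

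A small set of genes moved far in the knockout livers. A1cf, an RNA-binding cofactor of apolipoprotein B mRNA editing, fell from 26.6 ± 2.72 RPKM in controls to 0.47 ± 0.153 RPKM in knockout samples (SD, n = 4 each), a log2 fold change of -4.81 ± 0.14 (SE, limma adjusted p = 7.04e-09). Hmgcl, which makes ketone bodies in mitochondria, fell from 211 ± 16.7 to 47.5 ± 7.21 RPKM (-2.15 ± 0.11, limma adjusted p = 2.55e-06). Ehhadh, a peroxisomal enzyme of fatty acid oxidation, fell from 614 ± 176 to 138 ± 18.2 RPKM (-2.12 ± 0.17), and the fatty acid hydroxylase Cyp4a14 fell from 1551 ± 469 to 244 ± 86.9 RPKM (-2.66 ± 0.28). In the other direction Thrsp, a gene of lipid synthesis, rose from 22.3 ± 5.46 to 146 ± 52.1 RPKM (2.62 ± 0.30, limma adjusted p = 0.00223), and Gpnmb, a gene of lipid-laden macrophages, rose from 12.4 ± 5.34 to 46.8 ± 5.90 RPKM (1.99 ± 0.31).

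The other genes among the 10 largest falls were Cyp2b10 (-1.99), Cyp2b13 (-1.77), Cyp2c53-ps (-1.69), Zap70 (-1.66), Cyp3a16 (-1.43) and Krt23 (-1.42), given as log2 fold changes. The other genes among the 10 largest rises were Serpina12 (2.26), Tff3 (2.20), Pcp4l1 (2.09), Cxcl2 (1.89), Lrtm2 (1.86), Mup20 (1.80), Ccl21a (1.78) and Gbas (1.71). By the rule that chose these 20 genes, the 4 knockout samples lay on one side of the 4 controls in each. Cyp2b10 was listed at 0 in 3 knockout samples. Mup20, Ccl21a and the Cyp2b, Cyp2c, Cyp3a and Cyp4a genes have near-identical relatives, so their reads may have been divided among copies and their values are uncertain. The call of Cyp3a16 was lost without control 1, knockout 1 or knockout 4, where its limma adjusted p reached 0.0642, and that of Ccl21a without knockout 1 or knockout 4, where it reached 0.0527, and in a test chosen after the data were seen, with reads thinned to the shallowest library (0.0723). The other 18 genes kept their calls without each sample in turn.

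**Figure D1:**
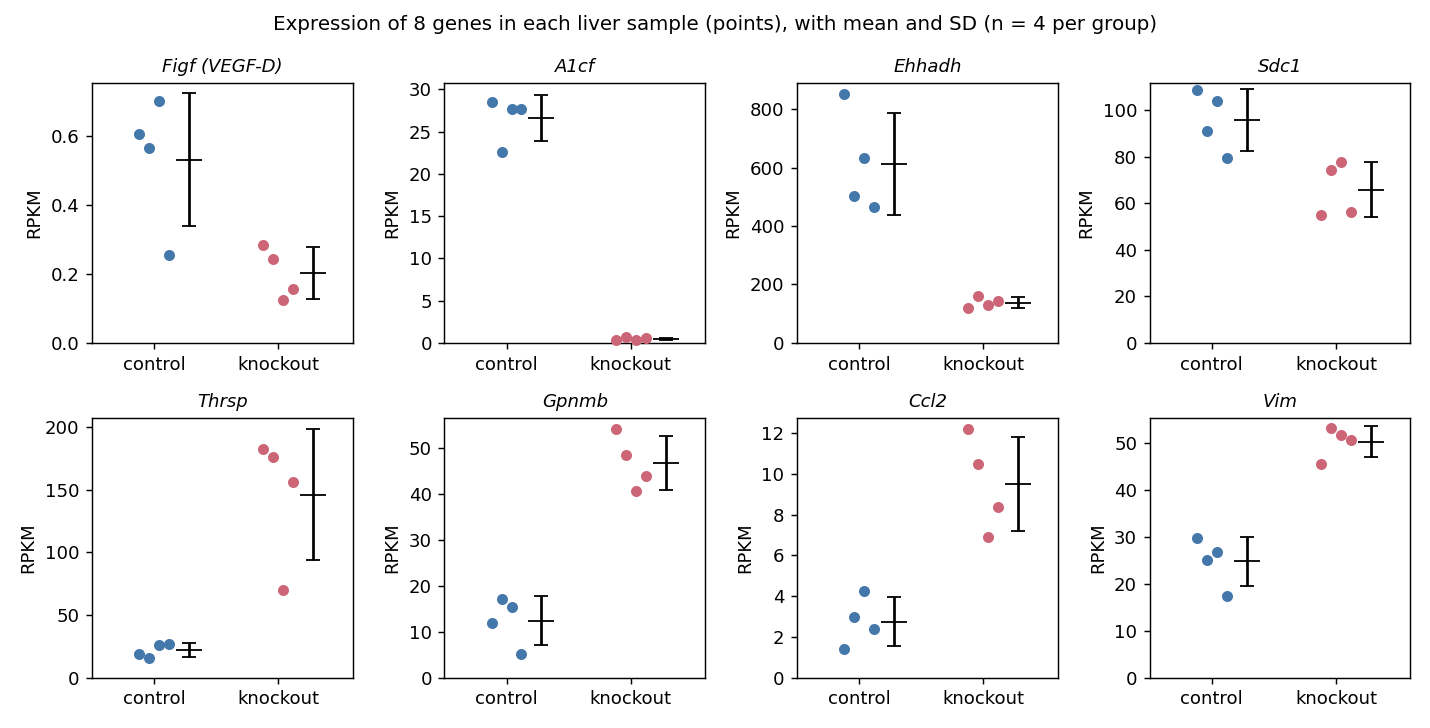
RPKM of 8 genes in each of the 4 control and 4 knockout liver samples (points, vertical axes from 0), with the group mean and SD beside them. A1cf averaged 26.6 RPKM in controls and 0.47 RPKM in knockout samples, while Gpnmb averaged 12.4 and 46.8 RPKM. The groups of Figf overlapped. Vim was chosen for the plot after its values were seen, in place of Col3a1, whose call was lost when some samples were left out.

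Of 12865 genes tested with limma, 994 (7.73%) changed at a Benjamini-Hochberg adjusted p under 0.05. Of these, 569 rose and 425 fell, and 164 changed at least 2-fold, 113 up and 51 down. The groups were completely separated in 2079 genes (16.2%), against 2.86% by chance, and 942 of the changed genes were among them. The direction of the calls depended on scaling: 57.2% of calls were rises as deposited, 42.2% after median-ratio scaling (441 rose, 604 fell) and 46.7% after quantile normalization (431 rose, 491 fell). Fewer genes passed with fewer samples, at 595 without control 1, 602 without control 3, 630 without knockout 1, 632 without knockout 2 and 539 without knockout 4. The first principal component (35.3% of the variance) parted the groups, while control 4 stood apart on the second (14.7%), and 749 genes changed without it.

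Genes that handle remnant particles were compared because the series is about their clearance. Sdc1, the heparan sulfate proteoglycan that takes up remnants in hepatocytes, fell from 95.8 ± 13.2 to 65.8 ± 11.9 RPKM (SD, n = 4 each), a log2 fold change of -0.55 ± 0.14 (limma adjusted p = 0.0355). Apoc2, the activator of lipoprotein lipase, rose from 552 ± 89.4 to 868 ± 67.6 RPKM (0.66 ± 0.12, limma adjusted p = 0.00797). Lpl, the lipase itself, rose by 0.43 ± 0.10 (limma adjusted p = 0.0277), and hepatic lipase, Lipc, fell by 0.39 ± 0.10 (limma adjusted p = 0.0359). The calls of Sdc1, Lpl and Lipc lay near the threshold. Sdc1 was lost without control 1, control 2, control 3, knockout 1 or knockout 4, where its limma adjusted p was 0.0921, 0.0607, 0.0909, 0.0826 and 0.0970. It was also lost after quantile normalization (0.0502), without a filter (0.0562) and with limma without trend and robust moderation (0.0682). In the authors' deposited table the log2 fold change of Sdc1 was -0.59 with an FDR of 0.00237. Lpl was lost without any of control 2, 3 or 4 or knockout 2, 3 or 4 (highest adjusted p = 0.0749), without trend and robust moderation (0.0582) and with the replicate number as a block (0.0658). Lipc was lost without any sample but knockout 3 (highest adjusted p = 0.0932), without a filter (0.0538), without trend and robust moderation (0.0726), with the block (0.0750) and, in a test chosen after the data were seen, after removal of the trend with length, GC content and level (0.0652). Apoc2 passed without each sample in turn, with adjusted p from 0.00799 to 0.0278.

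The remaining genes chosen for remnant handling did not pass. The log2 fold change was -0.43 ± 0.16 for Ldlr (limma adjusted p = 0.117), whose transcript averaged 41.9 ± 6.91 RPKM in controls and 31.2 ± 6.83 RPKM in knockout samples although all animals lack the receptor. It was -0.39 ± 0.11 for Ndst1, an enzyme of heparan sulfate sulfation (0.0544), -0.17 ± 0.08 for Apoe (0.237), 0.19 ± 0.13 for Apob (0.381), -0.22 ± 0.10 for Apoc3 (0.207), -0.11 ± 0.13 for Apoa5 (0.647), -0.02 ± 0.11 for Lrp1 (0.929) and -0.02 ± 0.34 for Vldlr (0.983), with limma adjusted p in brackets. Ldlr passed without knockout 2 (limma adjusted p = 0.0459). Ndst1 passed without knockout 3 (0.0476), after median-ratio scaling (0.0315) and after quantile normalization (0.0454), and Apoc3 after quantile normalization (0.0422). In tests chosen after the data were seen, trend removal called Ndst1 (0.0309) and Apoc3 (0.0347), and recovered reads called Ndst1 (0.0279). Angptl3 and Angptl4, inhibitors of lipoprotein lipase, were at 0.02 ± 0.18 and -0.05 ± 0.14. Pcsk9 averaged 0.24 ± 0.114 and 0.51 ± 0.219 RPKM, under the level tested.

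As groups, the remnant receptors and proteoglycans did not move together. Of 21 measured members 2 rose, the HDL receptor Scarb1 and the glypican Gpc4, 1 fell, Sdc1, and 18 did not pass; adjusted over the list alone, 2 rose and 2 fell (camera adjusted p = 0.757). The balance of these calls depended on the processing: 0 rose and 2 fell, Sdc1 and Lrp5, after median-ratio scaling, where Scarb1 (0.0906) and Gpc4 (0.0503) were lost, while Gpc4 and Scarb1 rose and Lrp5 alone fell after quantile normalization. Without a filter 1 rose, Gpc4, and 0 fell; Lrp5 is named only after its values were seen. None of 23 genes of heparan sulfate synthesis and editing passed with limma, also adjusted over the list alone, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.487). The calls depended on scaling: 1 member, Ndst1, fell after median-ratio scaling and 2, Ndst1 and Glce, after quantile normalization and after trend removal. Without control 4 Glce fell, and without knockout 3 or with recovered reads Ndst1 fell. Fry's test of change in either direction gave an adjusted p of 0.0160 for this list, but it called 32 of the 36 lists and so does not single this one out. Of 25 apolipoprotein and assembly genes 3 rose, Apoc2, Apoa4 and Apobec1, the enzyme that edits apolipoprotein B mRNA with A1cf, and 1 fell, Apoh, with the same counts adjusted over the list alone (camera adjusted p = 0.185). Apoc2 alone rose after median-ratio scaling, after quantile normalization and without a filter, where the limma adjusted p of Apoa4 was 0.0726, 0.0714 and 0.0671 and that of Apobec1 0.0573, 0.0586 and 0.0645. Of 25 lipases and regulators 2 rose, Lpl and Lipe, and 2 fell, Lipc and Lmf1 (4 and 2 adjusted over the list alone, camera adjusted p = 0.900), while without a filter 1 rose, Lpl, and 0 fell, and after quantile normalization Lpl alone rose. Of 25 cholesterol synthesis genes only Hsd17b7 fell, by 0.79 ± 0.14, also adjusted over the list alone (camera adjusted p = 0.132, and 0.0428 without knockout 2), and 2 fell after median-ratio scaling, quantile normalization or array weighting, the other being Rdh11, named after its values were seen. Apart from Apoc2 and Hsd17b7, the calls in these lists were fragile. Scarb1 (0.33 ± 0.09) and Apobec1 (0.46 ± 0.12) were lost without any 1 sample, with limma adjusted p up to 0.131 and 0.112. Apoa4 was lost without any sample but knockout 3 (up to 0.115), Apoh without any but knockout 1 (up to 0.0826), and Lmf1 without any but control 1 (up to 0.123). Gpc4 was lost without control 1, control 2, knockout 3 or knockout 4 (up to 0.0755), and Lipe without control 1, 2 or 3 or knockout 2, 3 or 4 (up to 0.0844). Each of these 7 calls was also lost with limma without trend and robust moderation, with adjusted p from 0.0524 to 0.0922, and all but that of Apoa4 with the replicate block, up to 0.129.

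Many fatty acid oxidation genes and targets of PPARA, the nuclear receptor that drives them in fasting, fell in the knockout livers. Of 34 measured members 17 fell and none rose (23 fell adjusted over the list alone), with a median log2 fold change of -0.37. Besides Ehhadh and Cyp4a14, the fatty acid hydroxylase Cyp4a31 fell by 1.31 ± 0.16 and Acot1, an acyl-CoA thioesterase, fell by 1.25 ± 0.21. The list passed with camera (adjusted p = 1.95e-17) but not with an estimated correlation (adjusted p = 0.206). Fry, which does not compare a list with other genes, called it (adjusted p = 0.00595). The score of the list was lower in all 4 knockout samples than in all 4 controls, and control 4, at 0.04, was the control nearest to them. Without control 1, control 3 or knockout 4, 9 members fell, and 10 fell without trend and robust moderation or with the replicate block. Fatty acid and triglyceride synthesis genes went both ways: 6 of 35 rose, among them Thrsp and Pparg (0.92 ± 0.19), a driver of fat storage, and 7 fell, among them the elongase Elovl3 (-0.85 ± 0.15). Adjusted over the list alone 10 rose and 9 fell, and the list did not pass (camera adjusted p = 0.533). Without control 1 or control 3, 3 members rose and 4 fell; 3 rose and 5 fell without control 2 or knockout 1, and 4 rose and 4 fell without knockout 4 or without trend and robust moderation. With the replicate block 3 rose and 4 fell.

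Some hepatocyte genes of detoxification and of both ends of the liver lobule fell, and most of the genes measured for them did not pass. Of 30 xenobiotic and oxidative stress genes 6 fell and none rose (14 fell adjusted over the list alone), with examples in Cyp2c29 (-1.26 ± 0.20) and Gstm4, a glutathione transferase (-0.92 ± 0.13). Camera gave an adjusted p of 2.39e-08 and, with an estimated correlation, an adjusted p of 0.349. The score of control 4 was -0.088, apart from the other controls, and 3 members fell without control 1, knockout 1 or knockout 4. Of 23 pericentral genes 5 fell and none rose (11 adjusted over the list alone): Lhpp (-1.16 ± 0.15), Oat (-0.90 ± 0.14), Rgn, Cyp2c29 and, named only after its value was seen, Lect2. The camera adjusted p was 1.84e-07, and the adjusted p was 0.206 with an estimated correlation. Of 20 periportal genes 5 fell and 1 rose (6 and 1 adjusted over the list alone). The falls were the urea cycle enzymes Ass1 (-1.04 ± 0.12) and Cps1, Sdsl and, named only after their values were seen, Gls2 and Hsd17b13; the rise was Serpina12. Their camera adjusted p was 0.000256, and the adjusted p with an estimated correlation was 0.290. Periportal falls numbered 2 without control 1, 2 or 3 or knockout 4, 1 without knockout 1 and 3 without knockout 2. They numbered 2, Ass1 and Cps1, without a filter or without trend and robust moderation, 3 after quantile normalization and 1, Ass1, with the replicate block. The list scores gave an exact permutation p of 0.0571 for the xenobiotic and periportal lists and 0.0286 for the pericentral list, and fry called the pericentral (adjusted p = 0.00891) and periportal (0.0480) lists but not the xenobiotic list (0.0661).

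Of 30 bile acid and sterol transport genes 6 fell and none rose, while adjusted over the list alone 11 fell and 4 rose. The falls included Abcg8, a sterol exporter (-0.94 ± 0.14), and Abcc3, an exporter of bile acid conjugates (-0.66 ± 0.09). This list passed with camera (adjusted p = 0.00589), not with an estimated correlation (adjusted p = 0.396) and not after quantile normalization (adjusted p = 0.122) or, in a test chosen after the data were seen, trend removal (0.191). Its falls numbered 2 without control 1, knockout 1 or knockout 4, and 3 without control 3, without knockout 2 or without trend and robust moderation; 10 fell with array weights, and 1 rose after quantile normalization. In the same samples the markers of stellate cells had a median log2 fold change of 0.73 and those of macrophages one of 0.39.

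Many genes of stellate cells and fibrosis rose in the knockout livers. Of 29 measured members 14 rose and none fell (25 rose adjusted over the list alone), with a median log2 fold change of 0.73. Vim, an intermediate filament of mesenchymal cells, rose from 24.8 ± 5.21 to 50.2 ± 3.30 RPKM (1.03 ± 0.14), the basement membrane collagen Col4a2 rose by 0.83 ± 0.15 and the matrix proteoglycan Lum by 0.82 ± 0.13. The fibrillar collagen Col3a1 rose from 11.2 ± 3.59 to 24.1 ± 7.43 RPKM (1.07 ± 0.27, limma adjusted p = 0.0363), with knockout 1 (14.6 RPKM) below control 1 (15.0 RPKM). Its call was lost without control 2, 3 or 4 or knockout 2, 3 or 4 (limma adjusted p up to 0.0893), without trend and robust moderation (0.0539), with the replicate block (0.0935) and, in a test chosen after the data were seen, with recovered reads (0.0803). The camera adjusted p was 3.56e-13, with an estimated correlation the adjusted p was 0.213, and with fry it was 0.00595. The score was higher in all 4 knockout samples than in all 4 controls. Without control 4, knockout 2 or knockout 4, 9 members rose.

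Some inflammatory and macrophage genes rose, and most of those measured did not pass. Of 24 cytokine and chemokine genes 9 rose and none fell (13 rose adjusted over the list alone), led by Cxcl2, which attracts neutrophils, and by Ccl2, which attracts monocytes and rose from 2.75 ± 1.19 to 9.50 ± 2.32 RPKM (1.67 ± 0.25). Camera gave an adjusted p of 5.72e-07, with an estimated correlation the adjusted p was 0.206, and with fry it was 0.00595. The rises numbered 4 without control 1, knockout 1 or knockout 2 and 5 without control 4. Of 30 Kupffer cell and macrophage genes 9 rose and 1 fell (11 and 1 adjusted over the list alone). The rises included Gpnmb, Spp1 (1.58 ± 0.22), the elastase Mmp12 (1.42 ± 0.26) and Ms4a7 (1.35 ± 0.22), and the fall was the scavenger receptor Cd163, named only after its value was seen. Cd163 was the gene lost without control 1, 3 or 4 or knockout 1, 2 or 4, where 0 members fell, while 2 fell without knockout 3. It was also lost without a filter, with a pseudocount of 0.1, without trend and robust moderation and with the replicate block. The camera adjusted p was 0.000256 and the adjusted p with an estimated correlation was 0.480, and fry did not call the list (adjusted p = 0.0856). Its score did not part the groups (exact permutation p = 0.171), with 2 knockout samples above all controls, and control 4, at -0.59, was the lowest of the 8 samples.

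Of 30 acute phase genes 10 rose and none fell (15 adjusted over the list alone), among them the pentraxin Apcs (1.24 ± 0.17), with a camera adjusted p of 0.000181 and an adjusted p of 0.433 with an estimated correlation. Without knockout 1, 6 rose. Of 36 interferon-stimulated genes 7 rose and none fell (9 adjusted over the list alone), among them the guanylate-binding proteins Gbp2 (1.05 ± 0.18) and Gbp3 (0.88 ± 0.13). Camera gave an adjusted p of 0.00168 and, with an estimated correlation, an adjusted p of 0.449. Without control 2 or control 4, 4 rose.

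Other cell types were measured through smaller marker sets. Of 6 neutrophil genes 2 rose, S100a9 and Retnlg (4 adjusted over the list alone). The camera adjusted p was 0.0265, and the adjusted p was 0.349 with an estimated correlation and 0.035 with fry. The list did not pass without a filter (camera adjusted p = 0.241, with 13 members and a median of 0.20 against 1.02) or at a mean RPKM of at least 1 (0.0532). S100a9 was lost without control 3 or knockout 1, 2 or 3 (limma adjusted p up to 0.0657) and Retnlg without any sample but control 2 (up to 0.0882). Of 27 endothelial genes only Ccl21a rose, also adjusted over the list alone, and the list, with a median of 0.25, passed with camera (adjusted p = 0.00228), not with an estimated correlation (adjusted p = 0.493). Without control 4, whose score of -0.50 was the lowest, camera gave 0.0680; 2 endothelial genes rose without control 2, 3 without control 3, and 0 without knockout 1 or knockout 4. With scaling that left out the 50 highest genes 2 rose. Of 5 adipocyte genes 1 rose, Lipe (4 adjusted over the list alone; camera adjusted p = 0.0115, adjusted p = 0.349 with an estimated correlation), while 0 rose without control 1, 2 or 3 or knockout 2, 3 or 4, and 2 rose without control 4. Lipe was also lost without a filter, after quantile normalization, without trend and robust moderation and with the replicate block, with adjusted p up to 0.0750.

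Of 15 T and NK cell genes 1 rose, Ccl5, and of 8 B cell genes Cd74 rose and Jchain fell, with the same counts adjusted over each list alone, and neither list passed (camera adjusted p = 0.113 and 0.696), though the T and NK cell list did without a filter (0.0418) and after median-ratio scaling (0.0432). Ccl5 was lost without control 1, control 2, knockout 1, knockout 2 or knockout 4 (limma adjusted p up to 0.0736), Cd74 without control 2 or knockout 1, 2 or 4 (up to 0.0777), and Jchain without any sample but control 3 and knockout 3 (up to 0.110). Of 16 cholangiocyte genes Spp1 rose and Krt23 fell, also adjusted over the list alone (camera adjusted p = 0.900), and 2 rose without control 3. Of 9 red blood cell genes 1 fell, Alas2, also adjusted over the list alone (camera adjusted p = 0.132, but 0.0390 without control 1, 0.0265 without control 3 and 0.0439 without knockout 3). The pancreas and muscle sets had 3 measured members each and were not tested as lists; none of their members passed with limma, though 1 pancreas gene, Amy2b, fell adjusted over the list alone.

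**Figure D2:**
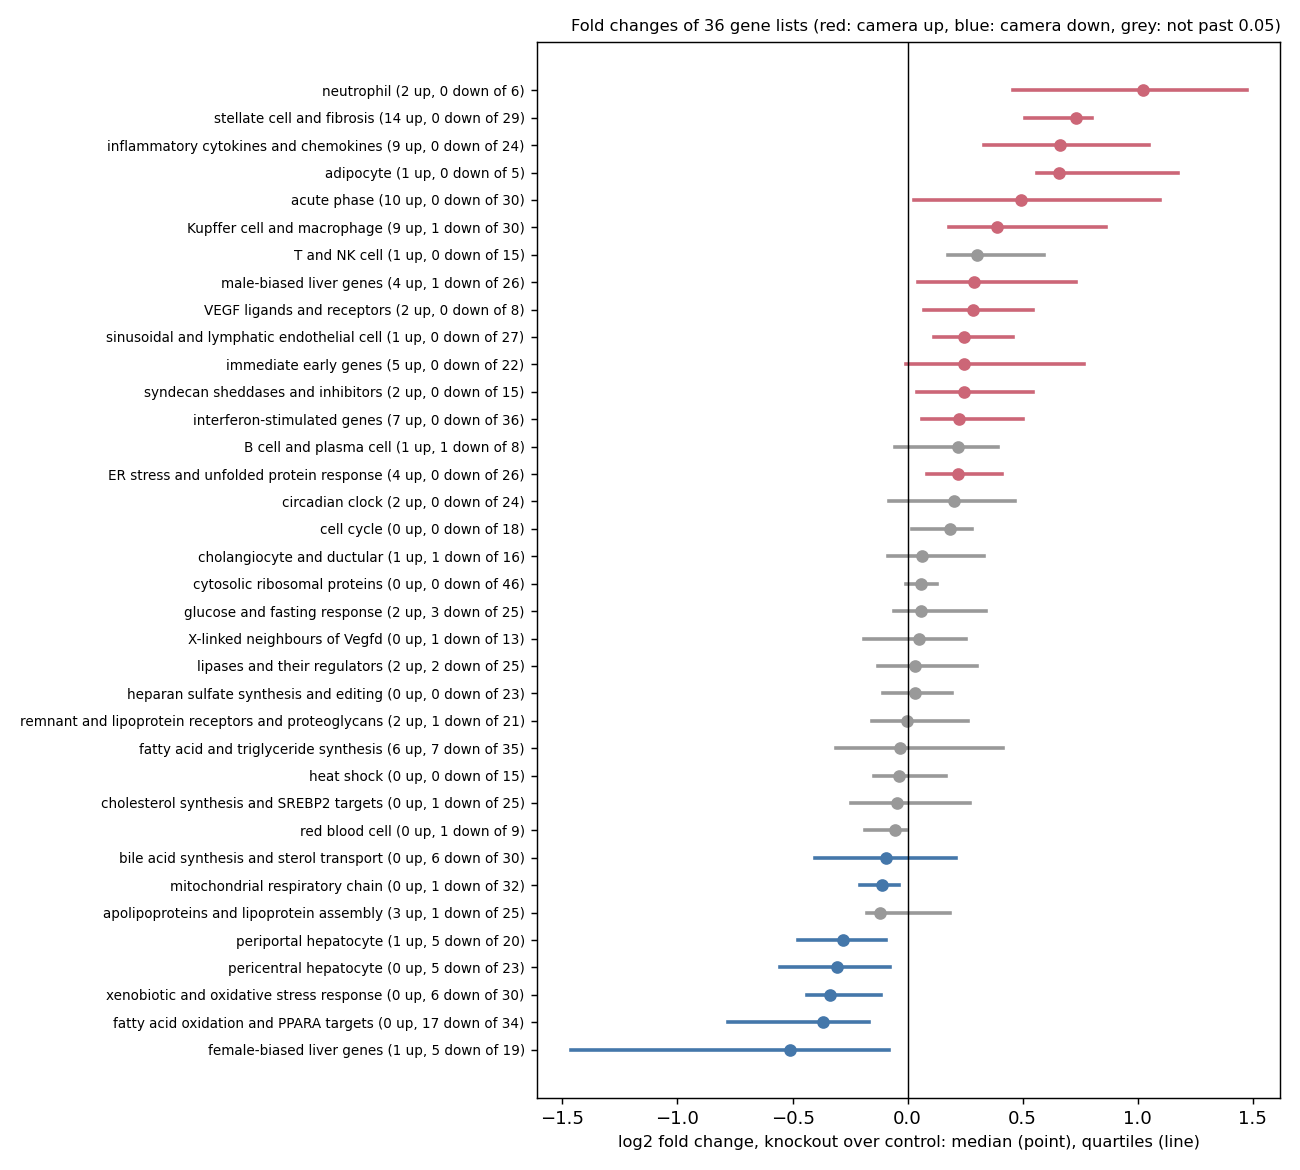
Median log2 fold change (points) and quartiles (lines) of the 36 gene lists tested, knockout over control on the log2(RPKM + 0.5) scale, with camera's calls at its preset correlation in red (13 up) and blue (7 down). The stellate cell and fibrosis list had a median of 0.73 and the fatty acid oxidation list one of -0.37; with an estimated correlation no list passed.

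Camera called 20 of the 36 lists with its preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.206 and 6 lists had an unadjusted p under 0.05. Fry, which asks whether a list's genes move and does not compare them with other genes, called 8 lists in a single direction and 32 in either direction. Dividing the same 8 samples otherwise, with control 4 and knockout 1 exchanged, gave 19 lists with the preset correlation, and the 18 divisions with 2 samples of each group on either side gave 1 to 13. The authors' deposited table held 1136 genes with an FDR under 0.05, 563 up and 573 down. Among the genes tested, 863 were called in the authors' deposited table and with limma in the same direction and 0 in opposite directions, 131 with limma only and 237 in the authors' deposited table only.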

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

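The tests of chromosomal position and of the share of hepatocytes, and those after trend removal and thinning, were chosen only after the results were seen. Of the 35 ways to split the 8 samples into 4 and 4, only the real split gave as many changed genes (994, highest other 2). The same held for rises (569, highest other 2) and falls (425, highest other 2). This share, 1 of 35, is the smallest that 35 splits allow, so it argues against chance for these counts without excluding it. The other splits count any real difference as spread within groups, which lowers their counts, so the size of the margin adds little. Any other difference between the groups, besides the knockout, could give the same result. The real split was also the only one, 1 of 35, with 20 gene lists (highest other 19). The real count ran from 17 to 21 when a sample was left out, so so small a margin does not exclude chance for this number. The highest other split exchanged control 4 and knockout 1. Like all 16 splits that exchange 1 sample of each group, which gave 7 to 19 lists, it carries part of the real difference. The 18 splits that exchange 2 samples of each group, and so balance the groups, gave 1 to 13 lists with at most 2 genes changed. At its preset correlation camera thus called lists also where the groups were balanced, so the call of a list by itself does not show a difference between the groups.

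Camera called the fatty acid oxidation and PPARA target list as fallen at its preset correlation, with a median log2 fold change of -0.37, but not with an estimated correlation (adjusted p = 0.206). A trend in transcript length, GC content and expression level is argued against as the whole cause, since the median was -0.30 after that trend was removed (camera adjusted p = 4.09e-12 at the preset correlation). A difference in depth is argued against as well, with a median of -0.36 and an adjusted p of 1.03e-17, again at the preset correlation, after thinning. Both arguments rest on the medians, since a call at the preset correlation by itself does not show a difference between the groups. A lower share of hepatocytes is argued against as the whole cause, since it would lower abundant hepatocyte transcripts as far as the list: the score of 10 such transcripts differed by 0.00083 between the groups, apart from a fall by the list's median (exact permutation p = 0.0286, the smallest that 4 against 4 allows, also without the 4 acute phase genes among them). The list score lay at -0.54 against them, with an exact permutation p of 0.0571 that misses the threshold. The test against the list's median was added after that miss was seen, and it ignores the spread of the list between samples. The 10 transcripts moved both ways, with log2 fold changes from -0.35 for Apoh (limma adjusted p = 0.0294) to 0.57 for Hpx (0.0549). A score near 0 thus does not mean that each stayed unchanged. As deposited, their median lay 0.37 above that of the list, with an SD of 0.28 among them. The median of the 10 transcripts lay within their SD of that of the list after quantile normalization (0.16 above, SD 0.22) and trend removal (0.24 above, SD 0.31). A smaller part played by that share thus stays open, as does the knockout, untested.

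Camera called the stellate, macrophage and inflammatory lists as risen at its preset correlation, but with an estimated correlation the adjusted p were 0.213, 0.480 and 0.206, and the macrophage score did not part the groups (exact permutation p = 0.171). A lower share of hepatocytes, which would raise all other cell types alike, is argued against as the whole cause for the stellate genes: their score rose 0.35 more than that of endothelial genes (exact permutation p = 0.0286, the smallest that 4 against 4 allows). The test covers only the stellate genes. The endothelial score itself rose by 0.32, with 4 knockout samples above all controls (exact permutation p = 0.0286), so a part played by that share stays open. At the preset correlation all 3 lists kept camera's call after the trend with transcript length, GC content and expression level was removed, and all 3 after the difference in depth between the libraries was thinned away. More stellate cells or higher expression in each may play a part.

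Genes with the largest falls, above all A1cf, lay below all controls in every knockout sample, as the rule that chose them required. A segment of the X chromosome carried along with the Vegfd allele is argued against only as a cause of these 10 falls acting on genes within it, since 0 of the 10 genes lie on chromosome X. An effect of such a segment on genes elsewhere was not tested. Among smaller falls, Pir (log2 fold change -1.32, limma adjusted p = 0.00459) and Alas2 (-0.52, 0.0158) do lie on chromosome X. Other X-linked changes, rises included, were not counted. Segments of another genetic background elsewhere cannot be told apart: 80 neighbouring pairs of tested genes were both called, between the median of 71 and the 95th percentile of 84 in 1000 shuffles, which leaves room for a few segments. Around the 10 genes 6 neighbours were called, against a median of 7 and a 5th percentile of 3 in sets of like expression, which again excludes no segment around a single gene. A variant acting on A1cf alone would leave no called neighbours and, like the knockout itself, stays open.

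In 19 of 316 groups of 4 values, 6.01%, a sample lay far from the other 3, close to the 1 in 20 that chance gives, and control 2 was that sample 6 times. The number given here is the gap to the nearest sample over the whole range of the group. Control 2 stood apart in A1cf (0.879), Apob (0.872), Apoh (0.869), Lrtm2 (0.905), Mogat1 (0.859) and the ribosomal protein score (0.917). Control 1 stood apart in Manf (0.904), and control 3 in Ifi44 (0.893) and the VEGF score (0.830). Control 4 stood apart in the cholangiocyte score (0.901) and the xenobiotic score (0.840). Knockout 1 stood apart in Acta1 (0.941), Apoh (0.896) and Cyp2b10 (1, the other 3 being at 0). Knockout 2 stood apart in Gbp2 (0.8292), Mogat1 (0.853) and the bile acid score (0.921), and knockout 3 in Cxcl2 (0.887) and Thrsp (0.836).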

How the results depend on the processing

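The tests with recovered reads, trend removal and thinning were chosen only after the data were seen. The count of 994 changed genes (569 up, 425 down) moved by over 1.5 times at a threshold of 0.1 (1774, with 1081 up and 693 down), through the threshold itself. It ran from 539 to 888 when a sample was left out (319 to 481 up, 220 to 407 down), where fewer samples were fitted. Without trend and robust moderation falls dropped to 280, and the cause was not tested. In every alternative, 0 genes called there and in the 994 had opposite directions. Of 94 named genes past the threshold none turned direction, 56 passed without each sample in turn, and 22 were lost with the replicate block, 23 without trend and robust moderation, 17 without a filter and 15 after thinning. The scalings moved the median of all genes by -0.0656 to 0.0184. Testing every row of the table moved nothing, since each symbol has 1 row.

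The replicate number as a block gave 583 changed genes, 336 up and 247 down. Over all tested genes, samples with the same number did not deviate together (correlations of -0.125, -0.0262, -0.0615 and -0.0198), which gives no sign of pairing. Samples with different numbers were not compared, and pairing that touches only some genes is not excluded.

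The log2 difference of Figf ran from -0.68 to -0.46 when a sample was left out and was -0.64 after quantile normalization, where the exact permutation p was 0.0286. Camera called 20 lists at its preset correlation and 0 with an estimated correlation. Fry, a test of another form that sets a list against no change and not against other genes, called 8. The values in brackets below are adjusted p for lists and log2 fold changes for genes, and the causes were not tested. With pseudocount 0.1, the log2 fold change turned or reached 0, uncalled, for Vldlr (0.0578). With no filter on low values, a list call was lost for VEGF (0.149), neutrophil (0.241) and male-biased (0.138), was gained by T and NK cell (0.0418), turned direction without a call for B cell (0.968). With mean RPKM at least 1, a list call was lost for neutrophil (0.0532), turned direction without a call for cholangiocyte (0.742). With median-ratio scaling, a list call was gained by T and NK cell (0.0432), turned direction without a call for ribosomal proteins (0.984). With median-ratio scaling, the log2 fold change turned or reached 0, uncalled, for Angptl3 (-0.036). With quantile normalization, a list call was lost for bile acid (0.122) and respiratory chain (0.141), was gained by ribosomal proteins (0.00215), turned direction without a call for remnant receptors (0.784), lipases (0.464), fatty acid synthesis (0.878) and glucose (0.539). With quantile normalization, the log2 fold change turned or reached 0, uncalled, for Apoe (0), Kdm5d (-0.018) and Lrp1 (0.024). With scaling without the 50 highest genes, the log2 fold change turned or reached 0, uncalled, for Lrp1 (0). With an estimated correlation, a list call was lost for VEGF (0.379), sheddase (0.290), PPARA (0.206), bile acid (0.396), acute phase (0.433), inflammatory (0.206), interferon (0.449), stellate (0.213), Kupffer (0.480), neutrophil (0.349), sinusoidal endothelial (0.493), male-biased (0.705), female-biased (0.379), ER stress (0.472), immediate early genes (0.449), xenobiotic (0.349), periportal (0.290), pericentral (0.206), adipocyte (0.349) and respiratory chain (0.433). Fry made no call, where camera did, for VEGF (0.0534), bile acid (0.0922), acute phase (0.0667), interferon (0.0667), Kupffer (0.0856), sinusoidal endothelial (0.119), male-biased (0.264), female-biased (0.0667), ER stress (0.0888), immediate early genes (0.0667), xenobiotic (0.0661), adipocyte (0.0599) and respiratory chain (0.156), it made a call, where camera did not, for T and NK cell (0.0178), its direction, uncalled, differed from camera's direction against other genes for remnant receptors (0.615), heparan sulfate (0.969), lipases (0.447), fatty acid synthesis (0.865) and glucose (0.579). With recovered reads with limma voom, a list call was lost for VEGF (0.108) and male-biased (0.052). With recovered reads with limma voom, the log2 fold change turned or reached 0, uncalled, for Vldlr (0.14). With length, GC and level trend removed, a list call was lost for VEGF (0.159) and bile acid (0.191), was gained by ribosomal proteins (0.0426), turned direction without a call for remnant receptors (0.606), lipases (0.360), fatty acid synthesis (0.630), glucose (0.496) and heat shock (0.991). With length, GC and level trend removed, the log2 fold change turned or reached 0, uncalled, for Angptl4 (0.015), Kdm5d (-0.024) and Lrp1 (0.0868). With reads thinned to the shallowest library, a list call was lost for VEGF (0.118) and male-biased (0.051). With reads thinned to the shallowest library, the log2 fold change turned or reached 0, uncalled, for Vldlr (0.044). Leaving out each sample gave adjusted p of 0.000487 to 0.177 for ER stress, 0.0166 to 0.116 for VEGF, 0.327 to 0.960 for X-linked neighbours, 0.653 to 0.978 for cholangiocyte, 0.0428 to 0.300 for cholesterol, 0.0372 to 0.394 for circadian clock, 0.0257 to 0.947 for ribosomal proteins, 0.699 to 0.962 for glucose, 0.0323 to 0.960 for heat shock, 0.00128 to 0.0847 for immediate early genes, 0.615 to 0.943 for lipases, 0.000168 to 0.521 for male-biased, 0.0265 to 0.822 for red blood cell, 0.615 to 0.976 for remnant receptors, 4.28e-05 to 0.068 for sinusoidal endothelial and 0.0107 to 0.0502 for sheddase, lists that changed side or direction at least once. It gave log2 fold changes of -0.0981 to 0.22 for Angptl3, -0.13 to 0.0694 for Angptl4, -0.0928 to 0.0504 for Lrp1 and -0.34 to 0.25 for Vldlr, none of them called. Depth of 3407000 to 5605000 reads leaves genes such as Figf and Pcsk9 at a few reads per sample.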

Other observations

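The test of the genes around Figf was chosen only after the fall of Pir was seen, and those with recovered reads, trend removal and thinning only after the data were seen. Some female-biased liver genes fell in the knockout livers, and most of those measured did not pass. Of 19 measured members 5 fell and 1 rose (7 and 1 adjusted over the list alone), with a median log2 fold change of -0.51. The falls were Cyp4a14, Cyp2b10, Cyp2b13, Cyp3a16 and, named only after their values were seen, Cyp3a44, with Atp6v0d2 as the rise. The camera adjusted p was 3.91e-05, the adjusted p with an estimated correlation was 0.379, and fry gave 0.0667. The score's exact permutation p was 0.0571, with 3 of 4 knockout samples below all controls. Control 4, at a score of -0.14, lay apart from the other controls, and without it 9 members fell. Of 26 male-biased genes 4 rose, Mup20, Nudt7 (1.38 ± 0.25), C8a and, named after its value was seen, Egfr, and 1 fell, Elovl3 (6 and 1 adjusted over the list alone). The camera adjusted p was 0.0378, and the adjusted p was 0.705 with an estimated correlation. This list did not pass without control 1 (adjusted p = 0.106), control 2 (0.521, with 3 rises and 3 falls), knockout 1 (0.0836), knockout 3 (0.0742) or knockout 4 (0.123), nor without a filter (0.138), with recovered reads (0.0520) or after thinning (0.0510), and control 4, at 0.34, had the highest score of the controls. The Y-linked genes Ddx3y and Kdm5d were at 18.3 ± 1.06 and 2.75 ± 0.352 RPKM in controls and at 20.8 ± 3.14 and 3.02 ± 0.579 RPKM in knockout samples (SD, n = 4 each).

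Camera called several signalling and stress sets as risen at its preset correlation, though most of their members did not pass. Fry called the set of syndecan sheddases and their inhibitors (adjusted p = 0.0119) but not the VEGF (0.0534) or ER stress (0.0888) sets. Of 8 VEGF ligands and receptors 2 rose, also adjusted over the list alone: Vegfa from 38.0 ± 3.64 to 59.8 ± 9.07 RPKM (0.64 ± 0.12) and its coreceptor Nrp1 by 0.83 ± 0.16 (camera adjusted p = 0.0414, adjusted p = 0.379 with an estimated correlation). With camera the list did not pass without control 1 (0.0584), control 2 (0.0611), control 4 (0.0779), knockout 1 (0.116) or knockout 4 (0.0619), nor without a filter (0.149), with recovered reads (0.108), after trend removal (0.159) or after thinning (0.118). Of 15 syndecan sheddases and inhibitors 2 rose, Timp3 (0.85 ± 0.17) and Timp2, both inhibitors of metalloproteinases (6 rose adjusted over the list alone; camera adjusted p = 0.0231, adjusted p = 0.290 with an estimated correlation, 0.0502 with camera without control 2). Timp2 was lost without control 2, control 4 or knockout 1, 2 or 4 (limma adjusted p up to 0.0793). Of 26 ER stress genes 4 rose, Xbp1 (0.62 ± 0.12), Sec61b (0.76 ± 0.11), Atf3 and Manf, and adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.0238, adjusted p = 0.472 with an estimated correlation). Without control 1 camera gave 0.177 and without knockout 4 it gave 0.0571; without control 4, 6 rose and 1 fell, and Manf was lost without knockout 1, 2 or 4 (up to 0.0633).

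Of 22 immediate early genes 5 rose, Atf3 (0.93 ± 0.18), Btg2 (0.92 ± 0.17), Dusp1, Ier3 and, named after its value was seen, Ier5, and 7 rose adjusted over the list alone (camera adjusted p = 0.0180, adjusted p = 0.449 with an estimated correlation, 0.0847 with camera without knockout 2). Without control 1 or knockout 1, 2 or 4, 3 rose. Of 32 respiratory chain genes 1 fell, Sdhd, and 0 adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.000461, adjusted p = 0.433 with an estimated correlation, 0.141 with camera after quantile normalization). Sdhd was lost without control 1, 2 or 3 or knockout 1, 3 or 4 (limma adjusted p up to 0.0924).

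The lists of the circadian clock (2 of 24 rose, Rorc and Bhlhe40), glucose and fasting response (2 of 25 rose, Slc2a2 and Pfkfb3, and 3 fell, Gckr, Irs1 and, named after its value was seen, Igfbp2), cell cycle (0 of 18), heat shock (0 of 15) and ribosomal proteins (0 of 46) did not pass camera. With limma, 2 cell cycle genes, 1 heat shock gene and 2 ribosomal protein genes had an unadjusted p under 0.05. Their adjusted p were 0.222, 0.900, 0.305, 0.487 and 0.533. The clock list passed without knockout 3 (adjusted p = 0.0372), heat shock without control 1 (0.0323) and ribosomal proteins without control 2 (0.0257), after quantile normalization (0.00215) and after trend removal (0.0426). Rorc was lost without control 3 or knockout 1, 2 or 4 (limma adjusted p up to 0.0573), Bhlhe40 without any sample but control 3 (up to 0.0861), Pfkfb3 without any but knockout 3 (up to 0.110) and Irs1 without any but control 3 and knockout 3 (up to 0.106). Adjusted over each list alone, 5 clock genes rose and 1 fell, 3 glucose genes rose and 3 fell, and none passed in the other lists. Without a filter or without trend and robust moderation 1 clock gene rose, and 1 glucose gene rose and 1 fell; after median-ratio scaling 1 gene rose in each of these lists. Median, mean and camera's direction against other genes differed in sign for the fatty acid synthesis list (median -0.03, mean 0.14, camera down) and the heat shock list (median -0.04, mean 0.07, camera down). Camera's direction was also down for the lipase, glucose and heparan sulfate lists, whose medians were 0.03, 0.06 and 0.03, and for the list of X-linked neighbours (median 0.05, mean -0.06). The remnant receptor list had a median of -0.0037 and a mean of 0.014. The median of all tested genes was 0.06.

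Pir, which ends 534 bases before Figf begins on the same strand of the X chromosome, fell from 7.37 ± 0.973 to 2.75 ± 1.01 RPKM (SD, n = 4 each; -1.32 ± 0.20, limma adjusted p = 0.00459). Of 13 tested X-linked neighbours 1 passed over all genes, Pir, while 2 fell adjusted over the list alone (camera adjusted p = 0.505). Other choices called a neighbour besides Pir: 2 fell, Mospd2 and Pir, after median-ratio scaling, quantile normalization or trend removal, at a mean RPKM of at least 1 and without control 2 or knockout 2. S100g rose without control 1, 2, 3 or 4 and without a filter, and both it and Mospd2 are named only after their values were seen. An effect of the targeted locus on its neighbour, or a linked variant, may lie behind this. The other 6 tested genes within 1 Mb had a median log2 fold change of 0.14 and 0 passed, the nearest being Mospd2 (-0.55 ± 0.16, limma adjusted p = 0.0524). An effect on Pir alone needs no other gene to move, and Mospd2 lay near the threshold, so the test leaves the hypothesis open.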
